A study of Rattus norvegicus with 70 samples.

How the data were processed

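RNA was analysed from brown (BAT), subcutaneous (SAT) and visceral (VAT) adipose tissue of 24 Sprague-Dawley rats. Per the labels' protocols, rats arrived at 28 days of age, had 8 days to acclimate, were assigned to sham or PCB 52 at random and inhaled through the nose for 4 h daily over 28 days at an air flow of 12 L/min. About 100 mg of tissue was lysed, RNA was purified on columns, and RNA with an integrity number under 8 was excluded. The protocol names poly(A) capture or rRNA removal without saying which was used for a library. FastQC, HISAT2 and the rat build rn6 are named in the submitters' processing notes; their versions, the counting program and the annotation are not given in the sources used here. Whether strand was used in counting is also not given, so genes that overlap, antisense pairs and near-identical copies such as the globin genes Hbb, Hbb-b1 and Hbb-bs have uncertain counts.

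The authors deposited whole-number counts per gene, 1 table for each sex and depot, with 15319 genes in each of the 6 tables. The count table of female VAT was treated as one of estimated counts as deposited, because 5 lines under its genes hold spreadsheet summaries, 3 of them not whole; these lines name no gene and were left out, and its gene lines are whole and were used without rounding. No per-sample column was left unused. Genes are named by NCBI gene numbers, of which 15230 matched a RefSeq table of the GRCr8 assembly and 89 did not. That build differs from rn6, so no coordinates are printed, and the table served only for symbols, chromosome and gene order.

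Each library was placed in a group by its labelled tissue, sex and treatment. The numbers in the titles run from 1 to 24 and each keeps 1 sex and 1 treatment in every depot, so equal numbers were read as the same rat; the labels do not say this in words. Deviations from group means correlated with a median r of 0.074 over 68 pairs of libraries with the same number, 25 of them over 0.1, against -0.020 over 340 pairs with different numbers. The main depot tests had no term for the animal, and the fit with the animal as a block was an alternative. Of 170 pairs of libraries within groups, none were identical, and the lowest chi-square per gene was 7.33, above sampling noise, so no library was merged with another.

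Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default expression filter, robust dispersion estimation and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. PCB 52 was compared with sham within each sex and depot, over both sexes with sex as a term, and by the interaction of sex and treatment. In each sex an F test asked whether the effect differed among the 3 depots, and the sham groups of the sexes were compared in each depot. CPM values in the text are counts scaled to TMM-adjusted library sizes for gene means and to plain totals for single libraries. Fold changes are given as log2 of PCB 52 over sham, or of male over female, with standard errors. Median standard errors over genes were 0.180 in female BAT, 0.146 in male BAT, 0.331 in female SAT, 0.269 in male SAT, 0.153 in female VAT and 0.188 in male VAT.

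The comparisons, tests, 29 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. The lists of B and plasma cells and of the male tract had too few tested members in every sex and depot. Some lists share members, so their calls are not independent. The glucocorticoid response list shares Per1 with the circadian clock list and Dusp1 with the immediate early list. It shares Pdk4 with the thermogenic and fatty acid oxidation lists. The mean log2 CPM of each list per library was compared by a two-sided exact permutation test, which was added later. The naming rule took genes past the threshold by fold change, up to 10 each way, or the 5 of smallest p where under 4 passed; up to 4 members of each called list in order of p; and fixed genes of adipose function and xenobiotic metabolism. The text prints the leading members of each called list rather than all of them, and list members named for losing or turning their direction without 1 library, and genes of libraries that stood apart, were chosen after their values were seen. In the sham sex comparisons the 5 largest each way were named. Some genes that this rule names are not reported here.

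Correlations of fold changes across genes used differences of mean log2 CPM with a prior count of 2, and their p-values came from 100 reassignments of animals. Animals were reassigned once for both depots where depots of one sex were compared, so that the shared animals were kept in the permuted values. As a check on simulated data, counts were drawn from the libraries' own means, dispersions and sizes with 100 genes changed by 2-fold and 100 by 4-fold. The share of 2-fold changes recovered was 57% in female BAT, 71% in male BAT, 11% in female SAT, 15% in male SAT, 85% in female VAT and 49% in male VAT. For 4-fold changes it was 89%, 97%, 70%, 73%, 96% and 84% in the same order.

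Alternatives were DESeq2 size factors, no filter, a stricter filter of 1 CPM, robust estimation off, DESeq2 1.42.0, limma voom with sample weights, all libraries of a depot in one fit, 1 surrogate variable from sva 3.50.0, the animal block, and each library left out in turn. Leaving out 7 libraries together, the exact tests of list means and leave-one-out fits of lists were added after seeing the data; the 7 libraries were chosen from marker transcripts, ribosomal share and genes at 0. Changes of lists across alternatives were followed for called lists only. Unusual libraries were sought with Dixon's test in groups of 4 to 10 on 3 library measures (total count, genes at 0, ribosomal protein share) and on the fixed and depot marker genes, 139 tests in all. Splits of the samples into groups of the same sizes were drawn 100 times for each count of calls, and between sham sexes they were also counted for genes on the numbered chromosomes alone, which was added after the counts were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.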

Results

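Adipose RNA-seq libraries were compared between adolescent Sprague-Dawley rats, an outbred laboratory stock, that inhaled PCB 52 through the nose and rats of a sham group. PCB 52 is a chlorinated biphenyl, a class of persistent industrial chemicals found in indoor air. The series asks how gene expression in fat changes after sub-acute inhalation of this congener. Exposure lasted 4 h a day for 28 days and started at 39 days of age in males and 42 days in females, so that sex and age at the start differed together. Brown adipose tissue (BAT), the heat-producing depot, subcutaneous adipose tissue (SAT) and visceral adipose tissue (VAT) were taken from 24 rats. The 70 libraries formed 12 groups of sex, depot and treatment. Each group held 6 libraries, except female SAT sham with 5 and male VAT PCB 52 with 5. Libraries with the same title number were read as one animal, which the labels do not say in words.

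Total counts per library ran from 4604116 in male BAT to 9707132 in female VAT. BAT libraries were the shallowest, with 4916430 to 7124557 in female PCB 52, 4991736 to 6115021 in female sham, 4604116 to 7813842 in male PCB 52 and 4993333 to 7235645 in male sham. SAT totals were 6747050 to 8039051 in female PCB 52, 6967432 to 8381507 in female sham, 6719692 to 7803687 in male PCB 52 and 6506450 to 7943640 in male sham. VAT totals were 7173808 to 9707132 in female PCB 52, 6470081 to 7872768 in female sham, 7103395 to 7821120 in male PCB 52 and 6478976 to 8412797 in male sham. A count of 0 therefore allowed up to 0.309 to 0.652 CPM (counts scaled to library size) in a single library. Intervals and floors of this kind cover counting error only.

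Ucp1, the brown fat uncoupling protein, had a median of 5601 CPM in female BAT and 6238 CPM in male BAT. Elsewhere medians were at most 0.132 CPM. Adipoq, which encodes the adipocyte hormone adiponectin, was found in all 70 libraries, from 301.5 CPM in one male SAT library to 9219 CPM in one female VAT library. Csn1s1, a milk casein gene of mammary epithelium, ranged from 491.6 to 25010 CPM in female SAT and from 0.548 to 213600 CPM in male SAT. Ckm, the creatine kinase of muscle, ranged from 19.9 to 6991 CPM in female BAT and from 51.7 to 7263 CPM in male BAT. These ranges mark non-adipose transcripts that differed strongly between libraries of one group, as the plot of marker transcripts shows.

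**Figure D1:**
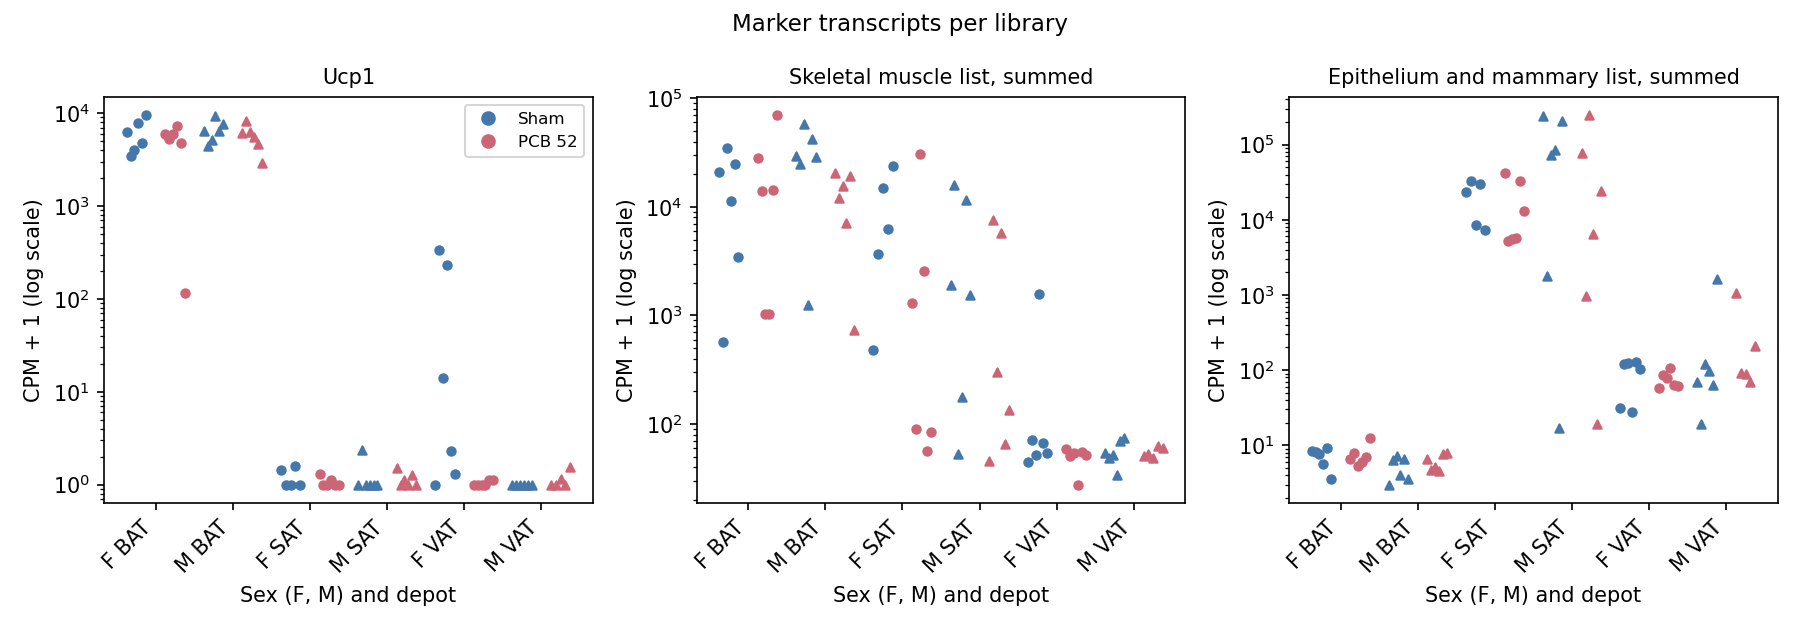
Marker transcripts in each of the 70 libraries, by sex and depot on the x axis; circles are females, triangles males, and the y axis is CPM + 1 on a log scale. Ucp1 sits near 5601 CPM in female BAT with one PCB 52 library at 113.6 CPM, while muscle and mammary transcripts vary widely within groups.

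Several libraries stood apart. Female BAT PCB 52 animal 24 had Ucp1 at 113.6 CPM, against 4779 to 7351 CPM in the rest of its group, and Ckm at 6991 CPM. Female SAT sham animal 8 had 27.8% of its counts on ribosomal protein genes, against 6.99% to 9.13% in the rest of its group. In male SAT PCB 52 animal 19, Mup4, a major urinary protein gene, reached 51790 CPM. Ucp1 reached 337.7 CPM in female VAT sham animal 4 and 229.5 CPM in animal 8. Svs4, a seminal vesicle secretory protein gene, was at 142.2 CPM in male VAT sham animal 11, and at 289.5 CPM in male VAT PCB 52 animal 23. Male VAT PCB 52 animal 13 had no reads on 255 of 262 expressed X-linked genes, on 2 of 2 expressed Y-linked genes and on 240 of 360 expressed genes of chromosome 9. Values without 7 of these libraries, chosen after the data were seen, are given for called lists where they end the call, turn the direction or move the median by more than 1.5 times; male VAT PCB 52 animal 23 was not among the 7.

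**Figure D2:**
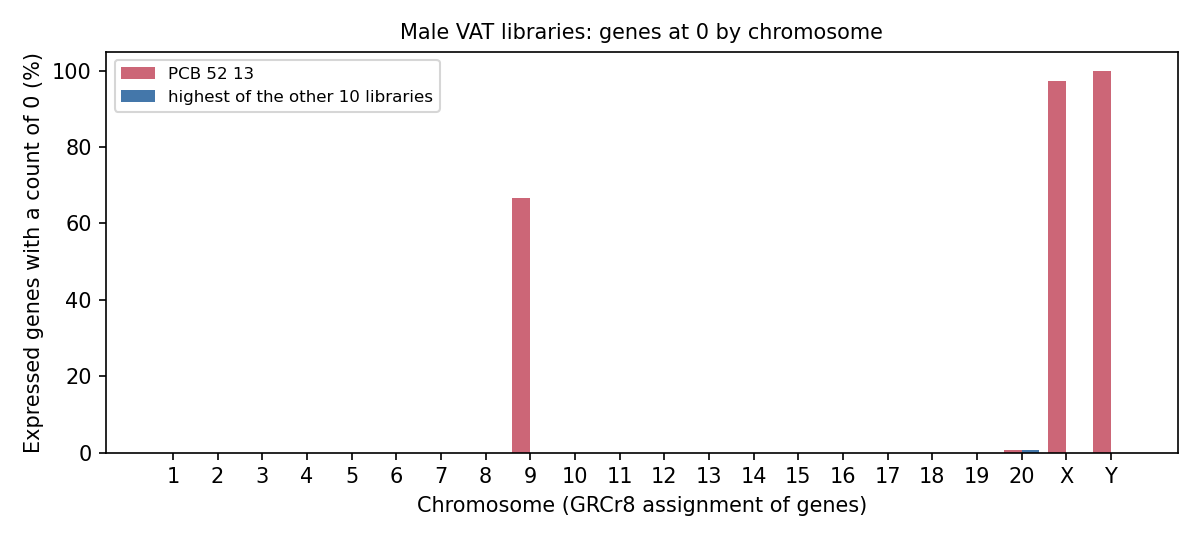
Percentage of expressed genes with a count of 0 on each chromosome in male VAT PCB 52 animal 13 (red bars) and the highest percentage in any other male VAT library (blue bars). In animal 13, 97.3% of expressed X-linked genes and 66.7% of those on chromosome 9 were at 0.

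In female BAT, glucocorticoid response genes, which corticosteroid hormones induce in most tissues, fell together after PCB 52. Of 21 tested members, 20 had a negative log2 fold change, with a median of -0.41 (camera with a preset correlation, adjusted p = 3.11e-15; adjusted p = 0.0391 with an estimated correlation). Errfi1 (gene 313729), a feedback inhibitor of the EGF receptor, was at 45.7 ± 10.8 CPM (SD, n = 6) after PCB 52 and 110.2 ± 49.0 CPM (n = 6) in sham, a log2 fold change of -1.27 (SE 0.262). Tsc22d3 (gene 83514), which encodes the anti-inflammatory protein GILZ, was at 117.6 ± 25 CPM against 199.4 ± 48.6 CPM, a log2 fold change of -0.76 (SE 0.185), and all 6 PCB 52 libraries lay below the sham mean for each of these genes. Adjusted over the list alone, 6 members passed, all lower; over all genes tested, none of the 21 did.

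Immediate early genes, which respond within minutes to stimulation, fell in female BAT, with 18 of 22 members lower and a median of -0.24 (adjusted p = 3.30e-06; adjusted p = 0.159 with an estimated correlation). The phosphatase gene Dusp1 stood at a log2 fold change of -0.78 (SE 0.227) and the transcription factor gene Maff at -0.97 (SE 0.309). Dusp1 is also a member of the glucocorticoid response list, as is the clock gene Per1. Circadian clock genes fell, with 12 of 16 members lower, a median of -0.22 and Per1 at -0.45 (adjusted p = 0.00836; adjusted p = 0.0980 with an estimated correlation). Endothelial genes of the vessel lining fell, with 15 of 21 members lower, a median of -0.14 and Esam at -0.31 (adjusted p = 0.0287; adjusted p = 0.895 with an estimated correlation). Cell cycle genes rose, with 16 of 17 members higher, a median of 0.25 and the mitotic kinase gene Aurka at 0.76 (adjusted p = 0.00121; adjusted p = 0.849 with an estimated correlation). Cholesterol synthesis genes rose, with 16 of 24 members higher and a median of 0.05 (adjusted p = 0.0191; adjusted p = 0.462 with an estimated correlation). Among them Nsdhl stood at 0.31 (SE 0.0949).

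The library of animal 24, with its low Ucp1 and high Ckm, lay in the PCB 52 group of this comparison. Without it the cell cycle median was -0.05 (adjusted p = 0.590), the endothelial median was -0.07 (adjusted p = 0.211), and the glucocorticoid median was -0.34, with an adjusted p = 0.165 under the estimated correlation. With 1 of the 12 libraries left out, the call also ended in 5 fits for cholesterol synthesis and 7 for endothelial genes, with the highest adjusted p-values without sham animal 4 (0.146, median 0.049, and 0.220, median -0.09). The circadian clock median was -0.12 without sham animal 12 (adjusted p = 0.0388), and the cholesterol median was 0.16 without sham animal 2. Single genes did not pass: edgeR's quasi-likelihood test called 0 of 10686 genes, and DESeq2 and limma voom also called 0. With edgeR 388 genes had an unadjusted p under 0.05, against 534 expected by chance. The 5 smallest unadjusted p-values, none past the adjustment (adjusted p = 0.999 for each), belonged to Errfi1, the cation channel gene Trpv4 (log2 fold change -0.95, SE 0.20), the red cell membrane gene Gypc (0.42, SE 0.0906), the endosomal protein gene Plekhf1 (-0.43, SE 0.0948) and the lipid droplet gene Pnpla3 (0.99, SE 0.222).

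In male BAT, interferon response genes of antiviral defence rose after PCB 52, with 27 of 29 members higher and a median log2 fold change of 0.29 (camera, adjusted p = 8.99e-06; adjusted p = 0.603 with an estimated correlation). The antiviral GTPase gene Mx2 was at 37.9 ± 13.4 CPM (SD, n = 6) against 22.5 ± 4.75 CPM (n = 6), and the chemokine gene Cxcl10 at 4.73 ± 1.59 CPM against 2.89 ± 0.49 CPM. Macrophage genes rose, with all 23 members higher and a median of 0.33 (adjusted p = 0.000308; adjusted p = 0.725 with an estimated correlation). The cytokine gene Il1b stood at 0.68 (SE 0.230) and the leukocyte membrane gene Cd53 at 0.54 (SE 0.228). T and NK cell genes rose, with all 9 members higher, a median of 0.33 and the kinase gene Lck at 0.54 (adjusted p = 0.0312; adjusted p = 0.603 with an estimated correlation).

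Immediate early genes fell in male BAT, with 15 of 22 members lower and a median of -0.19 (adjusted p = 0.000224; adjusted p = 0.603 with an estimated correlation). Klf2 (gene 306330), a flow-responsive transcription factor of endothelium, was at 67.1 ± 13.3 CPM (SD, n = 6) against 111.2 ± 11.4 CPM (n = 6), a log2 fold change of -0.73 (SE 0.125), with all 6 PCB 52 libraries below the sham mean. Klf2 and Dusp1 (-0.67, SE 0.143) were the 2 members lower when adjusted over the list alone. Endothelial genes fell, with 17 of 21 members lower, a median of -0.13 and Eng at -0.35 (adjusted p = 0.00636; adjusted p = 0.603 with an estimated correlation). Oxidative phosphorylation genes of the respiratory chain fell, with 33 of 34 members lower, a median of -0.10 and Ndufs7 at -0.36 (adjusted p = 0.00344; adjusted p = 0.900 with an estimated correlation). Skeletal muscle genes fell, with all 22 members lower and a median of -1.39 (adjusted p = 2.53e-08, or 0.603 with an estimated correlation, exact p of the list mean 0.372). The oxygen carrier gene Mb stood at -1.16 (SE 0.363), while Ckm ranged from 51.7 to 7263 CPM in sham and from 58.4 to 2379 CPM after PCB 52.

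With 1 of the 12 libraries left out, the call ended in 4 fits for oxidative phosphorylation (median -0.01, adjusted p = 0.586 without PCB 52 animal 23), 3 for T and NK cell genes (0.25, adjusted p = 0.104 without the same library) and 1 for endothelial genes (-0.09, adjusted p = 0.0929 without sham animal 3). Without animal 23 the interferon and macrophage medians were 0.15 and 0.19. Medians of lists that stayed called were -0.07 for endothelial genes without PCB 52 animal 21, -0.12 for immediate early genes without animal 13, -0.21 for oxidative phosphorylation without animal 15 and 0.51 for T and NK cell genes without sham animal 3. No gene passed in male BAT with edgeR, which tested 10687 genes and had 1054 at an unadjusted p under 0.05 and 0 after adjustment. By chance 534 would be expected at the unadjusted level. DESeq2 called 8 genes, 3 higher and 5 lower, limma voom called 0, and edgeR called 1 without PCB 52 animal 19. After Klf2, the smallest p-values belonged to the growth factor gene Igf2 (-0.72, SE 0.130), the telomerase-associated gene Tep1 (0.36, SE 0.0762), the interferon-inducible gene Parp9 (0.51, SE 0.109) and Dusp1, with edgeR adjusted p-values of 0.397 for Klf2 and Igf2 and 0.434 for the rest. In simulated data built on these libraries, edgeR recovered 71% of genes changed by 2-fold and 97% of those changed by 4-fold.

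In female SAT, some lists of adipocyte genes were called higher after PCB 52 and others were not. Lipolysis and adrenergic signalling genes rose, with 18 of 22 members higher and a median of 0.49 (camera, adjusted p = 5.82e-06; adjusted p = 0.601 with an estimated correlation). Fatty acid synthesis genes rose with 18 of 25 higher and a median of 0.18 (adjusted p = 0.00632), and mature adipocyte genes with 13 of 22 higher, a median of 0.30 and a mean of 0.034 (adjusted p = 0.0205; adjusted p = 0.601 with an estimated correlation for both lists). Fatty acid oxidation genes were not called, with a median of -0.05 (adjusted p = 0.204). Other adipocyte genes went the other way without passing: Adipoq stood at -0.35, Lep at -0.53 and Cfd at -2.20, values that were 0.53, 0.59 and 0.14 without sham animal 8. Insulin and glucose handling genes rose with 19 of 23 higher and a median of 0.35 (adjusted p = 0.00322), and extracellular matrix genes with 20 of 26 higher and a median of 0.22 (adjusted p = 0.0205). With an estimated correlation the adjusted p was 0.601 for both. Adrb3, the beta-adrenergic receptor that drives lipolysis, was at 18.7 ± 8.28 CPM (SD, n = 6) against 5.52 ± 4.28 CPM (n = 5). Dgat2, the last enzyme of triglyceride synthesis, was at 531.8 ± 163.7 CPM against 274.3 ± 104.7 CPM, and the transcription factor gene Cebpa at 232.0 ± 55.3 CPM against 164.0 ± 17.6 CPM. The growth factor gene Igf1 stood at a log2 fold change of 0.60 (SE 0.290), the matricellular gene Ccn2 at -1.22 (SE 0.461) and the fibronectin gene Fn1 at 0.55 (SE 0.289).

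Glucocorticoid response genes fell in female SAT, with 18 of 21 members lower and a median of -0.37 (adjusted p = 0.000585; adjusted p = 0.601 with an estimated correlation). The metallothionein gene Mt2A was at 103.6 ± 89.5 CPM (SD, n = 6) against 324.6 ± 155.2 CPM (n = 5), and the kinase gene Sgk1 at 55.4 ± 20.6 CPM against 131.2 ± 111.4 CPM. Skeletal muscle genes fell, with all 20 members lower and a median of -0.69 (adjusted p = 6.96e-08; adjusted p = 0.601 with an estimated correlation). Epithelium and mammary gland genes fell, with 21 of 24 lower and the whey protein gene Wap at 47.2 ± 44.6 CPM against 355.6 ± 318.5 CPM (adjusted p = 0.000617; adjusted p = 0.601 with an estimated correlation). Oxidative phosphorylation genes fell, with 25 of 34 lower and a median of -0.36 (adjusted p = 0.00322; adjusted p = 0.601 with an estimated correlation). Adjusted over the list alone, no member of the 9 called lists passed.

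Sham animal 8, the library rich in ribosomal protein transcripts, lay in the sham group of this comparison, and its Ckm was at 4231 CPM. Without it the oxidative phosphorylation median was 0.0079 (adjusted p = 0.606), Tnnt1, a slow troponin gene, turned from -2.68 to 2.62, and Cfd, the adipocyte protease adipsin, turned from -2.20 to 0.14. In the same fit 21 of 22 mature adipocyte genes were higher, with a median of 0.46 and a mean of 0.43 (adjusted p = 1.99e-12; adjusted p = 0.441 with an estimated correlation). Other lists stayed called there with smaller medians: 0.30 for lipolysis, 0.17 for insulin, 0.07 for extracellular matrix, -0.20 for epithelium and -0.45 for skeletal muscle. With 1 of the 11 libraries left out, the call ended in 6 fits for mature adipocyte genes (median 0.28, adjusted p = 0.399 without sham animal 2), 4 for extracellular matrix (0.15, adjusted p = 0.154 without sham animal 12) and 2 for fatty acid synthesis (0.075, adjusted p = 0.0594 without PCB 52 animal 24). The skeletal muscle median ran from -3.61 without PCB 52 animal 18 to -0.21 without sham animal 12. The glucocorticoid median was -0.23 without PCB 52 animal 22, and those of fatty acid synthesis and extracellular matrix were 0.40 and 0.34 without sham animals 2 and 10. With edgeR 0 of 11824 genes passed and 605 had an unadjusted p under 0.05, against 591 expected by chance. DESeq2 and limma voom called 0. The smallest p-values, with an adjusted p of 0.768 from edgeR, belonged to the protease inhibitor gene Spink8 (-2.20, SE 0.522), the thyrotropin receptor gene Tshr (0.93, SE 0.255), the peroxisomal transporter gene Abcd2 (0.73, SE 0.208), the acetyltransferase gene Nat8l (0.96, SE 0.273) and the matricellular gene Ccn1 (-1.18, SE 0.339).

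In male SAT, cholesterol synthesis genes rose after PCB 52, with 22 of 24 members higher and a median log2 fold change of 1.62 (camera, adjusted p = 1.47e-08; adjusted p = 0.532 with an estimated correlation). A single library carried this rise: without animal 19, whose Mup4 stood at 51790 CPM, the median was 0.04 (adjusted p = 0.971). Idi1, which encodes an isomerase of the sterol pathway, was at 1635 ± 3976 CPM (SD, n = 6) after PCB 52, against 11.9 ± 3.89 CPM (n = 6) in sham. Idi1 turned from a log2 fold change of 7.10 to -0.03 without that library.

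Cell cycle genes rose in male SAT, with 28 of 30 members higher and a median of 0.51 (adjusted p = 7.26e-07; adjusted p = 0.532 with an estimated correlation). Unfolded protein response genes rose, with 20 of 24 members higher, a median of 0.27 and the chaperone gene Hyou1 at 0.98 (adjusted p = 9.39e-05; adjusted p = 0.532 with an estimated correlation). Without animal 19 their medians were 0.18 (adjusted p = 0.169) and 0.07 (adjusted p = 0.101), and Aurka turned from 3.11 to -0.09. Granulocyte and mast cell genes fell, with 13 of 16 lower, a median of -0.16 and the IgE receptor gene Fcer1a at -0.62 (adjusted p = 0.000388; adjusted p = 0.532 with an estimated correlation). Interferon response genes fell, with 21 of 29 lower, a median of -0.14 and Rsad2 at -0.46 (adjusted p = 0.0106; adjusted p = 0.687 with an estimated correlation). Without animal 19 the medians of these lists were 0.012 (adjusted p = 0.287) and 0.05 (adjusted p = 0.365). The interferon call ended in 5 of 12 fits without 1 library, and its median was 0.028 without sham animal 11 (adjusted p = 0.50). Lymphoid transcripts were high in that library, where T and NK cell genes summed to 813.6 CPM and B and plasma cell genes to 897.4 CPM, against at most 180.9 and 84.9 CPM in the other shams. In PCB 52 animal 23 they summed to 2338 and 1907 CPM; without it the interferon median was -0.22, the cell cycle median 0.29 and the unfolded protein median 0.42. The granulocyte median was -0.54 without PCB 52 animal 17, and the interferon median -0.09 without animal 21.

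Extracellular matrix genes fell in male SAT, with 24 of 26 lower and a median of -0.31 (adjusted p = 5.74e-06; adjusted p = 0.532 with an estimated correlation). The collagen gene Col1a2 was at 13000 ± 7803 CPM (SD, n = 6) against 19130 ± 9958 CPM (n = 6), and the matrix protein gene Postn at 1526 ± 793.1 CPM against 2340 ± 1256 CPM. Without animal 19 the matrix median was -0.14 (adjusted p = 0.0224), and without animal 21 it was -0.66. Skeletal muscle genes fell, with all 18 members lower, and the calcium buffer gene Pvalb at 30.7 ± 46.8 CPM against 101.1 ± 133.1 CPM (adjusted p = 6.65e-08; adjusted p = 0.532 with an estimated correlation). The muscle median of -1.13 was -0.41 without sham animal 3 and -1.93 without PCB 52 animal 15. No member of the 7 called lists passed when adjusted over the list alone. With edgeR 0 of 11459 genes passed, 165 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Among the smallest p-values were those of Idi1, of Acp3 (6.34, SE 1.82), highest in animal 19, and of the GDNF receptor gene Gfra1 (-0.98, SE 0.301), with an edgeR adjusted p of 1 for each.

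In female VAT, glucocorticoid response genes fell after PCB 52, with 19 of 21 members lower and a median log2 fold change of -0.69 (camera, adjusted p = 5.19e-17; adjusted p = 0.0907 with an estimated correlation). Adjusted over the list alone, 16 members passed, all lower; over all genes tested, none did. The metallothionein gene Mt1 (gene 24567) was at 3.25 ± 0.755 CPM (SD, n = 6) against 7.54 ± 2.95 CPM (n = 6), a log2 fold change of -1.20 (SE 0.257). Sgk1 (gene 29517), a kinase that regulates sodium transport, was at 38.8 ± 9.50 CPM against 61.5 ± 8.71 CPM, and the transcription factor gene Klf9 (gene 117560) at 81.4 ± 12.5 CPM against 112.8 ± 11.1 CPM. Errfi1 stood at -0.88 (SE 0.213), and for these 4 genes all 6 PCB 52 libraries lay below the sham mean. Per library, the list mean was 6.03 ± 0.233 log2 CPM (n = 6) against 6.66 ± 0.281 (n = 6), with an exact permutation p of 0.00433 that became 0.113 adjusted over the lists. The same mean in female BAT was 6.10 ± 0.253 against 6.64 ± 0.233, with an exact permutation p of 0.00216, the smallest the 924 splits can give, and 0.0520 after adjustment. In female SAT the exact permutation p of the list mean was 0.338. The plot of the glucocorticoid response list shows the mean of its members in each library.

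**Figure D3:**
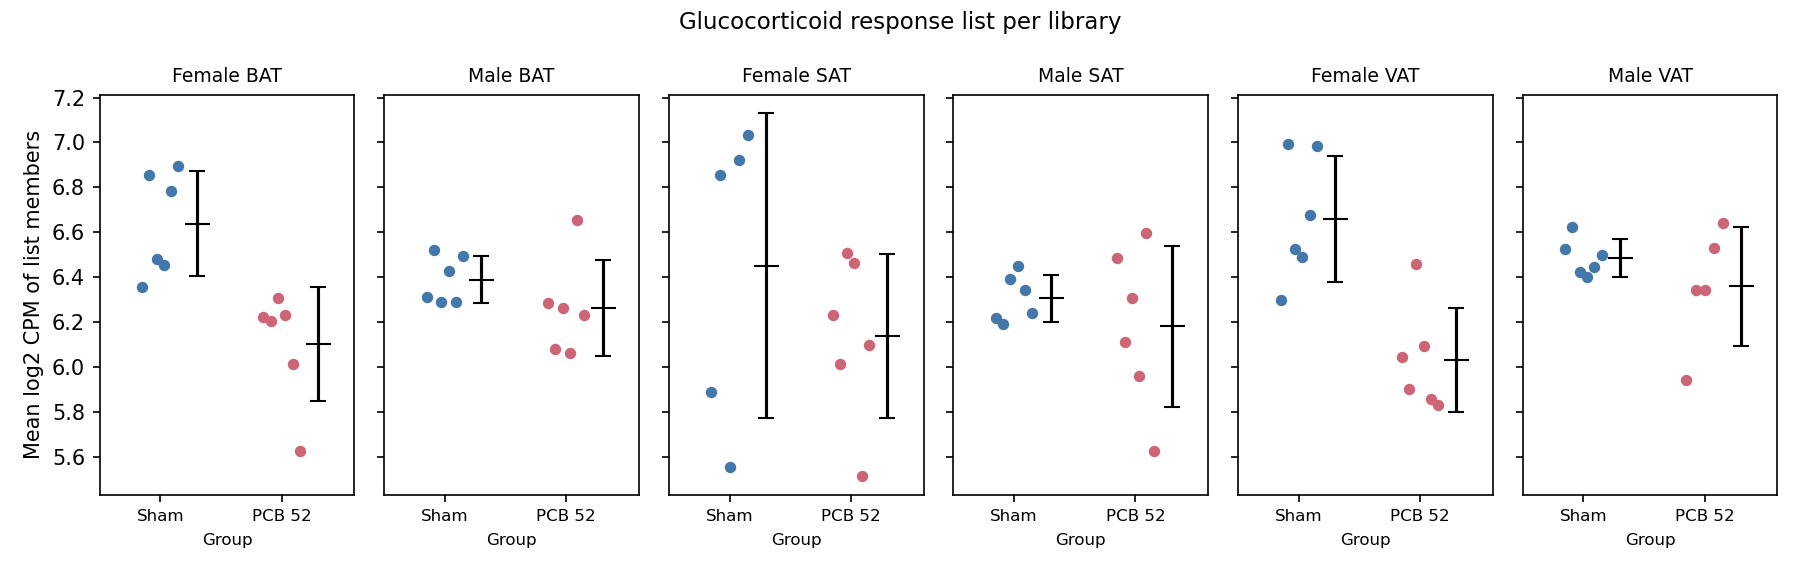
Mean log2 CPM of the glucocorticoid response list in each library (points), by treatment, in the 6 sex-by-depot comparisons; bars give the group mean ± SD. Female BAT fell from 6.64 in sham to 6.10 after PCB 52 and female VAT from 6.66 to 6.03.

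Immediate early genes fell in female VAT, with 19 of 23 members lower and a median of -0.23 (adjusted p = 0.000933; adjusted p = 0.663 with an estimated correlation). Nr4a3, an orphan nuclear receptor gene, was at 1.64 ± 1.07 CPM (SD, n = 6) against 12.9 ± 13.4 CPM (n = 6), and 2 members were lower when adjusted over the list alone. Circadian clock genes fell, with 12 of 16 lower, a median of -0.20 and Per1 at -0.84 (adjusted p = 0.00562; adjusted p = 0.663 with an estimated correlation). T and NK cell genes fell, with 7 of 8 lower, a median of -0.67 and Lck at -1.37 (adjusted p = 0.00361; adjusted p = 0.663 with an estimated correlation). Lymphoid transcripts were high in 2 sham libraries: B and plasma cell genes summed to 762.2 CPM in sham animal 10 and 437.8 CPM in sham animal 8, against at most 73.9 CPM in the other female VAT libraries. T and NK cell genes were highest in sham animal 10, at 280.8 CPM. Their median was -0.54 without animal 10 (adjusted p = 0.0374) and -0.47 without animal 8 (adjusted p = 0.0218). Endothelial genes fell, with 19 of 22 lower, a median of -0.16 and the transcription factor gene Erg at -0.37 (adjusted p = 0.00507; adjusted p = 0.663 with an estimated correlation). Erythroid genes of red blood cells fell, with all 6 lower, a median of -0.40 and the globin gene Hbb-bs at -0.46 (adjusted p = 0.0398; adjusted p = 0.663 with an estimated correlation).

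Thermogenic and brown adipocyte genes fell in female VAT, with 12 of 13 members lower and a median of -0.47 (adjusted p = 0.000746; adjusted p = 0.663 with an estimated correlation). Adjusted over the list alone, 4 were lower and 1 higher. The fatty acid carrier gene Fabp3 stood at -3.06 (SE 0.919), and Pdk4, the kinase that spares glucose from oxidation, was at 30.0 ± 7.47 CPM (SD, n = 6) against 94.0 ± 86.9 CPM (n = 6). Pdk4 also belongs to the lists of glucocorticoid response and fatty acid oxidation genes, and the clock gene Per1 to the former. Fatty acid oxidation genes fell, with 23 of 26 lower, a median of -0.22 and Ehhadh at -0.45 (adjusted p = 0.000933; adjusted p = 0.663 with an estimated correlation). Cholesterol synthesis genes rose, with 20 of 24 higher, a median of 0.29 and Fdft1, squalene synthase, at 0.51 (adjusted p = 9.27e-05; adjusted p = 0.663 with an estimated correlation). Interferon response genes rose, with 26 of 30 higher, a median of 0.24 and Gbp2 at 0.32 (adjusted p = 0.000933; adjusted p = 0.663 with an estimated correlation). Cell cycle genes rose, with 23 of 27 higher, a median of 0.29 and Tyms at 0.32 (adjusted p = 0.0164; adjusted p = 0.840 with an estimated correlation). Mesothelium genes of the peritoneal lining rose, with all 11 higher, a median of 0.46 and Rspo1 at 0.55 (adjusted p = 0.000678; adjusted p = 0.663 with an estimated correlation).

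Sham animals 4 and 8 of this comparison had Ucp1 at 337.7 and 229.5 CPM, with the mesothelial gene Wt1 at 8.81 and 9.07 CPM against a median of 41.3 CPM over female VAT. Without both, the medians were -0.12 for the thermogenic list (adjusted p = 0.395), 0.06 for fatty acid oxidation (adjusted p = 0.839) and -0.03 for mesothelium (adjusted p = 0.822). The calls for the circadian clock, interferon, endothelial and cell cycle lists also ended, with medians of -0.15 (adjusted p = 0.169), 0.08 (adjusted p = 0.428), -0.12 (adjusted p = 0.0747) and 0.13 (adjusted p = 0.395). The immediate early median moved to -0.44. Without animal 4 alone the thermogenic, interferon and mesothelium medians were -0.19, 0.15 and 0.22, all still called. With 1 of the 12 libraries left out, the call ended in 7 fits for erythroid genes (median -0.30, adjusted p = 0.259 without sham animal 4), 4 for the cell cycle (0.037, adjusted p = 0.753 without PCB 52 animal 20) and 1 each for fatty acid oxidation (-0.019, adjusted p = 0.283 without sham animal 4), endothelial (-0.08, adjusted p = 0.0880 without PCB 52 animal 20) and immediate early genes (-0.11, adjusted p = 0.0503 without sham animal 12). Medians of 0.75 for mesothelium without sham animal 12, 0.45 for the cell cycle without sham animal 6, 0.19 for cholesterol synthesis without PCB 52 animal 20 and -0.61 for erythroid genes without animal 18 were still called. With edgeR 0 of 11143 genes passed and 1066 had an unadjusted p under 0.05, against 557 expected by chance. DESeq2 called 51, of which 8 were higher and 43 lower, and limma voom called 0. Among the smallest p-values (edgeR adjusted p of 0.340 for each) were those of the mitochondrial carrier gene Slc25a25 (-0.91, SE 0.176), the reticulophagy gene Retreg1 (-1.07, SE 0.212), the reductase gene Akr1b10 (0.91, SE 0.181) and the bicarbonate transporter gene Slc4a7 (-0.95, SE 0.192).

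In male VAT, mesothelium genes rose after PCB 52, with all 11 members higher and a median log2 fold change of 1.28 (camera, adjusted p = 6.80e-11; adjusted p = 0.601 with an estimated correlation). The tight junction gene Cldn15 was at 19.1 ± 7.86 CPM (SD, n = 5) against 7.83 ± 5.00 CPM (n = 6), and Wnt2b, a Wnt ligand gene, at 23.4 ± 13.8 CPM against 8.19 ± 3.53 CPM. Interferon response genes rose, with 27 of 30 higher and a median of 0.30 (adjusted p = 2.71e-05; adjusted p = 0.601 with an estimated correlation). Oas2, a sensor of viral RNA, was at 18.5 ± 8.44 CPM against 6.54 ± 3.12 CPM, and Mx2 at 138.4 ± 68.7 CPM against 77.5 ± 19 CPM. Immediate early genes fell, with 21 of 23 lower, a median of -0.37 and Nr4a1 at -0.91 (adjusted p = 5.93e-05; adjusted p = 0.601 with an estimated correlation).

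Extracellular matrix genes fell in male VAT, with 21 of 26 lower and a median of -0.33 (adjusted p = 0.00216; adjusted p = 0.601 with an estimated correlation). Loxl1, an elastin crosslinking enzyme gene, was at 83.3 ± 18.7 CPM (SD, n = 5) against 175.9 ± 72.7 CPM (n = 6), and the proteoglycan gene Dcn at 872.9 ± 98.8 CPM against 1444 ± 588.9 CPM. Small rises were called for lipolysis genes (19 of 22 higher, median 0.18, Abhd5 at 0.33, adjusted p = 0.0129), fatty acid oxidation genes (18 of 27 higher, median 0.09, adjusted p = 0.0340), fatty acid synthesis genes (16 of 25 higher, median 0.13, Gpam at 0.50, adjusted p = 0.0396), insulin genes (17 of 23 higher, median 0.16, Hk2 at 0.54, adjusted p = 0.0396) and cholesterol synthesis genes (17 of 24 higher, median 0.12, Insig1 at 0.40, adjusted p = 0.0456). With an estimated correlation the adjusted p was 0.601 for each of these lists. Mature adipocyte genes rose, with 17 of 22 higher, a median of 0.13 and the activin receptor gene Acvr1c at 0.90 (adjusted p = 0.0340; adjusted p = 0.619 with an estimated correlation). Macrophage genes rose, with 15 of 24 higher, a median of 0.11 and Adgre1 at 0.61 (adjusted p = 0.0195; adjusted p = 0.601 with an estimated correlation). T and NK cell genes fell, with 14 of 17 lower, a median of -0.28 and Nkg7 at -0.84 (adjusted p = 0.0459; adjusted p = 0.601 with an estimated correlation). Oxidative phosphorylation genes fell, with 27 of 34 lower, a median of -0.19 and Ndufa2 at -0.53 (adjusted p = 0.0427; adjusted p = 0.663 with an estimated correlation).

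Svs4 was at 142.2 CPM in sham animal 11 and at 35.7 and 289.5 CPM in PCB 52 animals 13 and 23 of this comparison, and sham animal 7 had 8.02% of its counts on ribosomal protein genes. Animal 13 had no reads on 4 of 26 extracellular matrix members, all lower, and 6 of 34 oxidative phosphorylation members, 5 lower. Over other members, counted after these results were seen, the medians were -0.33 and -0.14. Without animal 13 they were -0.24 (adjusted p = 0.0904) and -0.16 (0.364), so both calls ended. Without animals 11 and 13 both were called, at -0.30 and -0.26 (adjusted p = 0.0278 each, or 0.67 and 0.719 with an estimated correlation). There the calls for mature adipocyte, fatty acid synthesis, fatty acid oxidation, macrophage and T and NK cell genes ended (adjusted p = 0.158, 0.0939, 0.0521, 0.0902 and 0.370, medians 0.12, 0.15, 0.12, 0.14 and -0.16). With 1 of the 11 libraries left out, the call ended in 7 fits each for cholesterol synthesis (adjusted p = 0.341 without PCB 52 animal 13) and T and NK cells (0.221 without PCB 52 animal 15). It ended in 5 each for mature adipocyte (adjusted p = 0.853 without sham animal 11), fatty acid oxidation (0.353), insulin (0.168, both without the same library) and macrophage genes (0.358 without sham animal 3). Fatty acid synthesis (adjusted p = 0.267 without PCB 52 animal 17) and oxidative phosphorylation (median 0.018, adjusted p = 0.682 without sham animal 7) lost it in 4 each, lipolysis (0.184 without sham animal 11) and extracellular matrix in 2 each. The interferon median was 0.073 without PCB 52 animal 23 (adjusted p = 0.0503), but 0.49 without animals 11 and 13 (adjusted p = 3.33e-10; adjusted p = 0.670 with an estimated correlation), where 11 members were higher when adjusted over the list alone. Medians still called were 0.34 for cholesterol and 0.21 for fatty acid synthesis without sham animal 11, 0.19 for fatty acid oxidation without sham animal 1 and 0.12 for lipolysis without PCB 52 animal 15. Without animal 13 they were 0.24 for mature adipocyte, 0.24 for insulin and 0.17 for macrophage genes. EdgeR called 0 of 11357 genes, with 715 at an unadjusted p under 0.05, DESeq2 5 (1 higher, 4 lower) and limma voom 0. The smallest p-values (edgeR adjusted p of 0.747 for each) belonged to Slc35g3 (1.77, SE 0.332), the tight junction gene Cldn11 (-3.67, SE 0.708), Prkaa2, a catalytic subunit of AMP-activated kinase (1.06, SE 0.222), Galnt16 (-1.04, SE 0.231) and Nr1h4, the bile acid receptor gene (-1.55, SE 0.373).

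**Figure D4:**
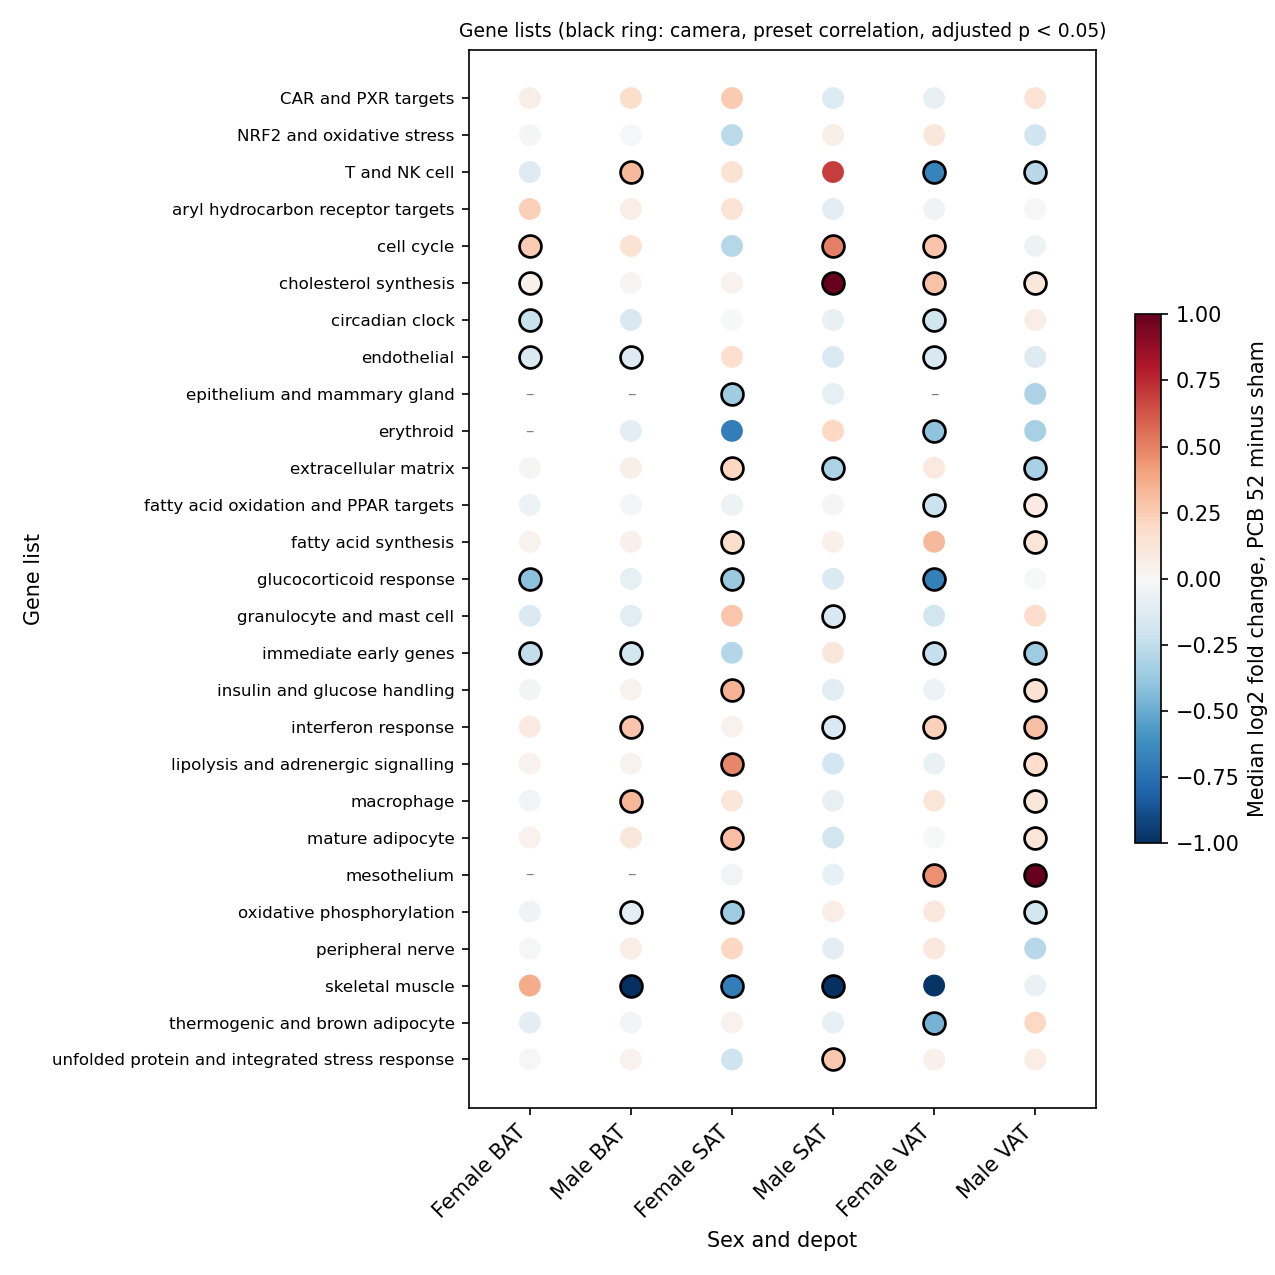
Median log2 fold change (PCB 52 minus sham, colour) of each gene list in the 6 sex-by-depot comparisons; a black ring marks an adjusted p under 0.05 by camera with the preset correlation, and a dash a list with under 5 tested members. Glucocorticoid response genes are blue with a ring in the 3 female depots, with medians of -0.41, -0.37 and -0.69. These depots were read as coming from the same females, so they are not 3 independent results.

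Targets of xenobiotic receptors were not called in any sex and depot. For aryl hydrocarbon receptor targets, which planar dioxin-like chemicals induce, the medians ran from -0.11 in male SAT (camera, adjusted p = 0.0592) to 0.24 in female BAT (adjusted p = 0.0545). For CAR and PXR targets, the receptors behind phenobarbital-like induction, they ran from -0.14 in male SAT (adjusted p = 0.0622) to 0.26 in female SAT (adjusted p = 0.204). Cyp1a1, the classic aryl hydrocarbon receptor target, stayed under the count filter in every comparison. None of the other fixed genes Ucp1, Adipoq, Lep, Pparg, Fasn, Cyp1b1 and Cyp2b1 passed in a comparison of PCB 52 with sham. In BAT, Ucp1 was at 4980 ± 2582 CPM (SD, n = 6) against 6119 ± 2619 CPM (n = 6) in females and at 5550 ± 1886 CPM against 6699 ± 1741 CPM in males. Leptin, Lep, was at 547.3 ± 151.5 CPM against 427.0 ± 126.8 CPM in female VAT and at 996.4 ± 185.7 CPM (n = 5) against 1072 ± 182.4 CPM (n = 6) in male VAT. The smallest unadjusted p among these genes was 0.0482 for Pparg in female SAT (log2 fold change 0.58, SE 0.263, edgeR adjusted p = 0.768).

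With both sexes in one model, 1 gene fell in BAT after PCB 52. Plekhf1 (gene 308543), which encodes an endosomal phosphoinositide-binding protein, was at 29.7 ± 4.19 CPM (SD, n = 12) against 39.7 ± 2.97 CPM (n = 12), a log2 fold change of -0.41 (SE 0.0704, edgeR adjusted p = 0.0490), with all 12 PCB 52 libraries below the sham mean. The total of calls was 0 with no filter on low counts, with robust estimation off or with 1 surrogate variable, 79 with DESeq2 and 51 with limma voom, and stayed above 0 for only 6 of the 24 libraries left out in turn: 12 without female sham animal 4, 3 without female PCB 52 animal 24, 2 without each of female PCB 52 animals 14, 16 and 20, and 1 without male PCB 52 animal 21. In SAT edgeR called 0 of 12157 genes, with 333 at an unadjusted p under 0.05 and 0 by DESeq2 and limma voom. In VAT it called 0 of 11664, with 804 at an unadjusted p under 0.05, 11 by DESeq2 and 1 by limma voom.

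Effects in the 2 sexes were compared by their interaction with treatment. No gene passed with edgeR: 0 in BAT with 266 at an unadjusted p under 0.05, 0 in SAT with 792 and 0 in VAT with 1243. DESeq2 called 18 genes in VAT and 0 in BAT and SAT, limma voom called 0 in each, and edgeR called 3 in VAT without male sham animal 1. Of 81 comparisons of a list's effect between sexes, none passed adjustment, and the smallest adjusted p was 0.766 by permutation. The glucocorticoid response list had an unadjusted permutation p of 0.0156 in VAT (male animal 13 included), the smallest of the 81, and 0.0232 in BAT. Whether these genes fell more in females is therefore not settled.

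Differences of the PCB 52 effect among depots were tested within each sex. With edgeR 0 of 12303 genes passed in females, with 1092 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom. In males 0 of 12218 passed, with 592 at an unadjusted p under 0.05, 0 by DESeq2 and 20 by limma voom. Across genes, which are not independent replicates, log2 fold changes correlated weakly between sexes and between depots. The 9 Pearson coefficients ran from -0.031 between sexes in VAT to 0.332 between sexes in BAT, with Spearman coefficients of -0.173 and 0.354. The smallest permutation p of the 9 was 0.148 for BAT and VAT of males (r = 0.143, rho = 0.240), and the smallest adjusted p was 0.751. Between the sexes in SAT the coefficient was 0.107, and 0.509 without the libraries that stood apart.

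Sham sex differences were broad in VAT. With edgeR 1291 genes differed in VAT between male and female sham rats, 693 higher in males and 598 higher in females. Acsbg1, an acyl-CoA synthetase gene, was at 73.5 ± 47.3 CPM (SD, n = 6) in males and 0.456 ± 0.501 CPM (n = 6) in females (edgeR adjusted p = 0.000370). Sult1d1, a sulfotransferase gene, was at 31.2 ± 16.3 CPM against 0.503 ± 0.343 CPM (edgeR adjusted p = 1.12e-05), and Aldh1a1, a retinal dehydrogenase gene, at 276.5 ± 474.1 CPM against 3.03 ± 1.40 CPM (edgeR adjusted p = 0.00276). The estrogen sulfotransferase gene Sult1e1 was at 33.0 ± 29.1 CPM in males and had no reads in any female library, where a count of 0 allows up to 0.464 CPM. Star, which carries cholesterol into mitochondria for steroid synthesis, was at 261.5 ± 82.1 CPM in females against 7.09 ± 7.49 CPM in males (edgeR adjusted p = 0.000204). The carboxypeptidase gene Cpa1 was at 94.7 ± 41.1 CPM against 2.19 ± 2.00 CPM (edgeR adjusted p = 4.94e-05), Bco1, a carotenoid-cleaving enzyme gene, at 19.7 ± 14.6 CPM against 0.272 ± 0.234 CPM, and the patterning gene Hoxc10 at 16.6 ± 3.66 CPM against 0.417 ± 1.02 CPM. For Acsbg1, Sult1d1, Aldh1a1, Star and Cpa1 all 6 male libraries lay on the same side of the female mean, with log2 differences of 7.23, 5.91, 6.51, -5.20 and -5.42. Ucma was also higher in males (log2 difference 5.44) and Dhrs7l1 in females (-5.57). Epididymis and male tract genes summed to 2870 CPM in male sham animal 11 of this comparison, against at most 24.2 CPM in the other male shams. Without that library the log2 difference was 4.80 for Aldh1a1 (edgeR adjusted p = 0.000550) and -9.90 for Hoxc10. The count of 1291 genes was 1356 without it and 677 without the libraries that stood apart.

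In SAT 127 genes differed between the sexes of the sham group, 40 higher in males and 87 higher in females. Pgr, the progesterone receptor gene, was at 28.4 ± 25.4 CPM (SD, n = 5) in females and 0.694 ± 0.437 CPM (n = 6) in males (edgeR adjusted p = 0.0137). Areg, an EGF receptor ligand gene of mammary epithelium, was at 66.1 ± 21 CPM against 1.35 ± 1.45 CPM (edgeR adjusted p = 0.0104), and the epithelial gene Lgals7 at 246.3 ± 490.0 CPM against 2.38 ± 1.42 CPM. The acute-phase gene Serpina3n was higher in males, at 490.5 ± 347.5 CPM against 35.1 ± 23.3 CPM, as were Adra2c, Pcdh17 and Acss2. In BAT 7 genes differed, 4 higher in males and 3 higher in females, of which 3 were X-linked, 2 Y-linked and 1 without a place in the RefSeq table. The 1 gene on a numbered chromosome was Nrarp, a Notch regulator gene, at 29.4 ± 4.80 CPM in males against 16.1 ± 2.36 CPM in females (edgeR adjusted p = 0.0238). For Pgr, Areg and Nrarp all 6 male libraries lay on the same side of the female mean, with log2 differences of -5.32, -5.60 and 0.87. The call for Nrarp ended with some single libraries left out, with the highest adjusted p of 0.113 without male sham animal 5. Those for Lgals7, Serpina3n, Adra2c, Pcdh17 and Acss2 ended likewise, with highest adjusted p-values of 0.110, 0.109, 0.0938, 0.0793 and 0.109, and the log2 difference of -6.68 for Lgals7 was -3.50 without female sham animal 8. In SAT 6 of the genes were X-linked and 2 Y-linked, and in VAT 44 and 2. Reads on the Y-linked genes Ddx3y or Eif2s3y were found in 34 of 35 male and 2 of 35 female libraries. In female VAT they reached 10 counts (1.35 CPM) for Ddx3y and 17 counts (2.30 CPM) for Eif2s3y. In female SAT the highest was 1 count, for Eif2s3y. Whether male RNA was mixed into a female VAT library was not tested. The depots cannot be ranked by these counts: limma voom called 3344 genes in SAT and 2157 in VAT, and simulated 2-fold changes were recovered for 3% of genes in SAT and 60% in VAT. Single libraries moved the SAT count of 127, to 563 without female sham animal 8, to 29 and 80 without female sham animals 6 and 10, and to 41, 15, 36 and 43 without male sham animals 3, 5, 7 and 9. The VAT count of 1291 was 844 without male sham animal 5 and 850 without female sham animal 8. Females and males also differed in age at the start of exposure, and each sex came in its own count table. Over all female VAT libraries Hoxc9 and the patterning gene Hoxc10 had medians of 25.75 and 19.92 CPM. Over male VAT libraries the medians were 6.525 and 0 CPM. The tissue label is VAT in both sexes. Whether the same part of this depot was sampled was not tested, so it cannot be told apart from sex.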

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

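The tests of low depth in male VAT PCB 52 animal 13, of animal 19 in male SAT and of other splits for gene counts, in all and on the numbered chromosomes, and the choice of the libraries that stood apart, were made after the results they measure were seen; the other tests of the 3 patterns were chosen after the pattern was seen but before their own result. Dixon's test singled out 16 values among 139 sets of libraries and measures, where chance gives about 1 in 20, or 7. No list passed the test for a different effect of PCB 52 between sexes, with the smallest adjusted permutation p of 81 at 0.766.

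Female BAT PCB 52 animal 24 lay far from its group in Ucp1 at 113.6 CPM (others 4779 to 7351), Pparg at 197.8 CPM (279.7 to 325.0), Zic1 at 25.3 CPM (13.1 to 15.9) and ribosomal protein share at 3.68% (2.35% to 2.77%). Female SAT sham animal 8 had 4211 genes at 0 (others 1733 to 1930) and a ribosomal protein share of 27.8% (6.99% to 9.13%). Female VAT PCB 52 animal 20 had a total of 9707132 counts (others 7173808 to 7823682) and a ribosomal protein share of 4.93% (2.48% to 3.15%). Female VAT sham animal 8 had Tbx15 at 4.74 CPM, against at most 0.128 CPM in its group. Male VAT sham animal 7 had a ribosomal protein share of 8.02% (2.71% to 3.38%).

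In males, Fasn was high in animal 17 in both SAT, at 31470 CPM (others 3719 to 7772), and VAT, at 4924 CPM (1791 to 2371). That SAT library had Csn1s1, a milk casein gene, at 213600 CPM; male SAT sham animals 1 and 11, with Csn1s1 at 205900 and 180900 CPM, had Fasn at 21700 and 21660 CPM. Hoxc10 was low in male SAT PCB 52 animal 19, at 0.744 CPM (7.43 to 16.9), and present in male VAT PCB 52 animal 13 at 3.77 CPM and male VAT sham animal 11 at 2.78 CPM, where the other libraries had at most 0.135 CPM. Ucp1 was at 1.38 CPM in male SAT sham animal 3 and at 0 in the rest of its group.

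Glucocorticoid response genes were lower after PCB 52 in BAT and VAT of females. Tissue of another kind in the libraries that stood apart is argued against as the whole cause, since without them the list median was -0.342 in BAT (exact p of the list mean 0.00433) and -0.700 in VAT (exact p 0.0143), though adjusted camera p was 0.165 and 0.156 with an estimated correlation. A shift in the time of day of collection stays open: the difference between 2 sets of clock genes of opposite phase gave an exact p of 0.796 in BAT and 0.524 in VAT, and the 95% intervals of the difference, -1.25 to 0.982 and -1.11 to 0.591, leave room for a shift, while in SAT of the same females the sets did differ (exact p = 0.0130, not adjusted over the 6 comparisons; interval -1.02 to -0.117). Deviations of the list mean from group means correlated between BAT and VAT of the same 12 females (r = 0.808, rho = 0.937). The permutation p was 0.00196, adjusted over 6 relations 0.00588, and r without 2 animals 0.822. With group means removed, this cannot tell if an animal's state caused the fall. In males the deviations ran opposite ways in SAT and VAT (r = -0.898, adjusted p = 0.00432), with animal 13, which lost reads, at the lowest VAT mean (5.943). Whether PCB 52 or handling lay behind the fall was not tested, as no hormone measurement was analysed.

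Male VAT PCB 52 animal 13 had 501 expressed genes at 0. A loss of reads or counts from 1 point of the chromosome order onward may account for this: a single break point between Sema4c and Cox5b parted 100% of the 360 expressed genes of chromosome 9 into 120 with reads and 240 at 0, while 10000 random orders reached at most 70.0%. Low RNA input or depth is argued against, since 0.0227% of expressed genes on the other chromosomes were at 0 and the library total was 7692693 counts. Gene order came from the GRCr8 assembly, and no biological explanation was tested.

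Cholesterol synthesis genes were higher after PCB 52 in male SAT, and 1 library may account for it. Without animal 19 the list median was 0.0402 (camera, adjusted p = 0.971), against 1.62 with it, so the other animals gave no call for an effect of PCB 52 on this list. That library held Mup4 at 51790 CPM and Krt14, a keratin gene of epithelium, at 2163 CPM, and its low Hoxc10 also sets it apart, which is consistent with tissue of another kind in the sample. Which tissue it was could not be settled from these tables.

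Other splits of the same animals into groups of equal size were drawn 100 times for each count. Where edgeR's real count was 0, all 100 splits give as many by construction, so they say nothing about chance. This was so for PCB 52 against sham in all 6 sex-by-depot comparisons, with a highest other count of 1 in female BAT, 81 in male BAT, 1 in female SAT, 710 in male SAT, 1 in female VAT and 266 in male VAT. It was also so for SAT over both sexes (highest other 126), VAT over both sexes (12), the sex interactions in BAT (315), SAT (620) and VAT (53) and the depot tests in females (130) and males (534). The few splits with many calls, 2 of 99 others with any in male SAT, point to a structure of the samples, which was not tested. For BAT over both sexes 3 of 100 splits gave at least the real count of 1, with the highest other at 2. A single gene passed there in the main setting, and the count was 0 with no filter. The share of splits was not adjusted over the counts tested, so chance is not excluded.

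For called lists chance could not be excluded in any comparison. As many lists were called in 94 of 100 splits in female BAT (real 6, highest other 15), 64 in male BAT (7, 13), 35 in female SAT (9, 14), 98 in male SAT (7, 20), 54 in female VAT (12, 18) and 12 in male VAT (13, 16). The median number of lists in the other splits was 9, 7, 7, 12, 12 and 8 in the same order. For sham sex differences 3 of 100 splits reached the real count in BAT (7, highest other 395), 2 in SAT (127, 410) and 1, the real split itself, in VAT (1291, 7). Sex-linked genes fix part of these counts. On the numbered chromosomes alone the real count was reached in 2 of 100 splits in SAT (118 genes, highest other 397), 1 in VAT (1243, 7) and 3 in BAT (1, 382). This argues against chance in VAT, where the highest other count was far lower. In SAT it is weaker evidence, since another split called more genes. For the single gene in BAT chance is not excluded. The splits with 395 genes in BAT and 410 in SAT again point to a structure of the samples, which was not tested.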

How the results depend on the processing

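The fits without the libraries that stood apart, the exact tests of list means and the leave-one-out fits of lists were chosen after seeing the data. Apart from single libraries left out, 205 alternative values were computed for the counts, correlations and list totals, of which 156 kept their direction and side of the threshold or stayed within 1.5 times the main value. Of 6760 alternative values of named genes, 6551 did, 78 lost and 20 gained significance, and 111 changed sign; of 209 alternative values of called lists, 28 did, 178 lost their call and 3 changed sign. Where no cause is named below, the cause was not tested. At these depths 10686 to 11824 of the 15319 genes passed the count filter in the sex-by-depot comparisons, and the rest were not tested. Simulated 2-fold changes were recovered for 11% of genes in female SAT and 15% in male SAT, the lowest of the 6 although BAT libraries had lower totals, and for 1% in the sex interaction of SAT.

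DESeq2 gave 8 genes in male BAT, 51 in female VAT, 5 in male VAT, 79 in BAT over both sexes, 11 in VAT over both sexes, 18 in the sex interaction of VAT and 3 in the depot test of females. Between sham sexes it gave 72 genes in BAT, 1043 in SAT and 2128 in VAT. Limma voom gave 51 genes in BAT over both sexes, 1 in VAT over both sexes, 20 in the depot test of males, and 12, 3344 and 2157 genes between sham sexes in BAT, SAT and VAT. For BAT over both sexes the count was 0 with no filter, robust estimation off or 1 surrogate variable and 3 without the libraries that stood apart, against 1 in the main test. With 1 surrogate variable VAT over both sexes gave 3. Without the libraries that stood apart the sham sexes differed in 563 genes in SAT and 677 in VAT.

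With the animal as a replicate block, a paired design over depots, the depot tests gave 0 genes in females and 0 in males, and the block changed no call.

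With an estimated correlation the number of called lists fell from 6 to 1 in female BAT and to 0 elsewhere. Fry and the exact permutation of list means gave 0 in all 6 comparisons. Without the libraries that stood apart the totals were 15 in female BAT, 4 in male SAT and 7 in female VAT. In those fits camera's direction turned for the oxidative phosphorylation list in female SAT, with a median of 0.0079, and in male SAT for the cholesterol synthesis list, with a median of 0.040, and the interferon response list, with a median of 0.048.

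For correlations of fold changes, Spearman's rho was -0.085 between sexes in SAT, -0.113 between BAT and SAT of males and -0.016 between SAT and VAT of males, where Pearson's r was positive. Without the libraries that stood apart r was 0.509 between sexes in SAT and 0.124 between SAT and VAT of females.

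Leaving out each library or animal in turn gave these lowest and highest values. Counts ran from 0 to 1 in male BAT, from 0 to 12 in BAT over both sexes, from 0 to 2 in VAT over both sexes (1 without female sham 2 or 6, and 2 without male sham 1), from 0 to 3 in the sex interaction of VAT, and from 0 to 1 in the depot test of females (1 without animal 12). Sham sex counts ran from 15 to 563 in SAT and from 844 to 1633 in VAT. Called lists ran from 5 to 15 in female BAT (highest without PCB 52 24), from 4 to 17 in male SAT (without PCB 52 19 and PCB 52 21) and from 6 to 13 in male VAT (lowest without sham 9). Of the 54 called lists, 23 kept their call in every fit without 1 library and 31 lost it in at least 1. Correlations ran from 0.131 to 0.541 between sexes in BAT, from 0.063 to 0.341 between BAT and VAT of females, from 0.009 to 0.308 between BAT and SAT of males, from 0.081 to 0.234 between BAT and VAT of males, from 0 to 0.282 between sexes in SAT, from -0.068 to 0.040 between sexes in VAT, from -0.005 to 0.318 between BAT and SAT of females, from -0.122 to 0.195 between SAT and VAT of females and from -0.004 to 0.115 between SAT and VAT of males.

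For genes named in the text or by the naming rule, log2 fold changes that changed sign with 1 library ran as follows. In BAT, Lep in females ran from -0.42 to 0.75, and in males Pparg from -0.035 to 0.05, Fasn from -0.16 to 0.12, Cyp1b1 from -0.30 to 0.17 and Cyp2b1 from -0.024 to 1.40. In female SAT, Adipoq ran from -0.55 to 0.53, Lep from -0.77 to 0.59, Cyp2b1 from -0.78 to 0.06, Cfd from -2.48 to 0.14 and Tnnt1 from -4.74 to 2.62. In male SAT, Idi1 ran from -0.028 to 7.39, Lep from -0.75 to 0.25, Pparg from -0.45 to 0.043, Fasn from -1.11 to 0.23, Cyp2b1 from -0.88 to 0.48 and Aurka from -0.087 to 3.45. In male VAT, Adipoq ran from -0.001 to 0.16, Pparg from -0.086 to 0.11, Cyp1b1 from -0.12 to 0.10 and Cyp2b1 from -2.12 to 0.45. In SAT over both sexes, Adipoq ran from -0.50 to 0.08, Lep from -0.61 to 0.20, Fasn from -0.12 to 0.54, Cyp1b1 from -0.15 to 0.33 and Cyp2b1 from -0.70 to 0.14.

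Other settings changed the sign of these log2 fold changes. With 1 surrogate variable, Lep was -0.094 in female BAT; Pparg -0.01, Fasn 0.074, Tcap 0.074 and Eno3 0.25 in male BAT; Adipoq 0.57, Lep 0.65, Cyp1b1 -0.76, Cfd 0.21, Ndufa2 0.093, Cox6c 0.041, Ndufb9 0.021 and Tnnt1 2.75 in female SAT; Cyp2b1 -0.059 in male SAT; and Adipoq 0.052 and Lep 0.17 in SAT over both sexes. With limma voom, Fasn was 0.034, Cyp1b1 -0.32 and Cyp2b1 -1.07 in male BAT, and Cyp2b1 -0.51 in BAT over both sexes. In female SAT voom gave Adipoq 0.57, Lep 0.64, Cfd 0.055, Cox6c 0.009 and Tnnt1 1.04, in male SAT Cyp2b1 -1.39 and Rrm2 -0.075, and in SAT over both sexes Adipoq 0.30 and Lep 0.35. For Cyp1b1 in male BAT, at 0.006 in the main test, the value was -0.009 with DESeq2 size factors, -0.004 with no filter, -0.003 with the stricter filter, -0.021 with DESeq2 and -0.006 with all libraries of the depot. Without the libraries that stood apart, Lep was -0.42 in female BAT, Adipoq was 0.53, Lep 0.59, Cfd 0.14 and Tnnt1 2.62 in female SAT, and Idi1 was -0.028, Lep 0.11 and Aurka -0.087 in male SAT. In the same setting Pparg was -0.02 in male VAT, Adipoq 0.22 and Lep 0.34 in SAT over both sexes, and Lep -0.047 in VAT over both sexes.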

Other observations

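The tests without the libraries that stood apart, of the clock gene contrast and of the glucocorticoid list between depots were chosen after the list results were seen. In female BAT without animal 24, 15 lists were called, against 6 with it, and they spanned several cell types. Macrophage genes were lower after PCB 52 with a median log2 fold change of -0.56 (camera, adjusted p = 3.83e-08; adjusted p = 0.415 with an estimated correlation). Extracellular matrix genes were lower with a median of -0.36 (adjusted p = 0.00150; adjusted p = 0.586 with an estimated correlation), and granulocyte and mast cell genes with a median of -0.39 (adjusted p = 0.00211; adjusted p = 0.490 with an estimated correlation). T and NK cell genes were lower at -0.27 and skeletal muscle genes at -0.49 (both adjusted p = 0.0479; adjusted p = 0.415 and 0.729 with an estimated correlation). Oxidative phosphorylation genes were higher, at 0.14 (adjusted p = 6.25e-05; adjusted p = 0.586 with an estimated correlation). Lists of adipocytes were higher as well: fatty acid oxidation at 0.14 (adjusted p = 0.00211), fatty acid synthesis at 0.12 (0.00505), mature adipocyte at 0.11 (0.00288), thermogenic at 0.09 (0.0108) and lipolysis at 0.05 (0.0321), with adjusted p-values of 0.490, 0.415, 0.415, 0.586 and 0.415 with an estimated correlation.

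In female VAT without sham animals 4 and 8, oxidative phosphorylation genes were higher with a median of 0.28 (camera, adjusted p = 1.09e-07; adjusted p = 0.857 with an estimated correlation). In female SAT without sham animal 8, granulocyte and mast cell genes were higher with a median of 0.48 (adjusted p = 8.15e-07; adjusted p = 0.441 with an estimated correlation), and immediate early genes were lower with a median of -0.35 (adjusted p = 2.02e-07; adjusted p = 0.441 with an estimated correlation). Macrophage genes were higher there, at 0.13 (adjusted p = 0.00105; adjusted p = 0.730 with an estimated correlation), the opposite direction to female BAT. Lists called only without the libraries that stood apart were also NRF2 genes in female VAT at 0.16 (adjusted p = 0.0323), fatty acid oxidation and circadian clock genes in male SAT at -0.07 each (0.0157 and 0.0224) and endothelial genes in male VAT at -0.18 (0.0273), with adjusted p-values of 0.857, 0.904, 0.707 and 0.670 with an estimated correlation.

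Clock genes were also read as the mean log2 CPM of 4 genes (Bmal1, Npas2, Clock and Nfil3) minus that of 6 genes of the opposite phase, among them Dbp, Nr1d1 and Per3. In female SAT this contrast was -2.57 ± 0.236 (SD, n = 6) after PCB 52 and -2.0 ± 0.389 (n = 5) in sham, with an exact permutation p of 0.0130, not adjusted over the 6 comparisons. In the other comparisons the exact p was 0.796 in female BAT, 0.403 in male BAT, 0.309 in male SAT, 0.524 in female VAT and 0.0671 in male VAT.

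Deviations of the glucocorticoid list mean correlated between SAT and VAT of females with r = 0.694 (rho = 0.718, permutation p = 0.0182, adjusted p = 0.0365, r without 2 animals 0.756) and between BAT and SAT with r = 0.576 (rho = 0.700, permutation p = 0.0651, adjusted p = 0.0977, r without 2 animals 0.687). In males r between SAT and VAT, with animal 13 included, was -0.898 (rho = -0.927, permutation p = 0.000720, adjusted p = 0.00432, r without 2 animals -0.871). Between BAT and VAT of males r was -0.129 (rho = -0.082, permutation p = 0.717, adjusted p = 0.717, r without 2 animals -0.158), and between BAT and SAT it was 0.497 (rho = 0.434, permutation p = 0.105, adjusted p = 0.126, r without 2 animals 0.050).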
